A study of Homo sapiens with 16 samples.

How the data were processed

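RNA of 16 cultures of the human triple-negative breast cancer line MDA-MB-231 was sequenced. All cultures carried a tet-off system, in which doxycycline silences the introduced gene. There were 4 stably transfected clones with 4 libraries each. Clones A and B carried an empty vector (EV_A and EV_B), and clones E11 and H3 carried tristetraprolin (TTP_E11 and TTP_H3). TTP, the product of ZFP36, is an RNA-binding protein that promotes decay of mRNAs with AU-rich elements. Per the labels' protocols, cells with TTP were maintained with doxycycline at 2 µg/mL, and a washout of this drug and of the selection drugs lasting 24 h or more came before each experiment. The labels state the maintenance in doxycycline only for the TTP clones, so it goes with the arm, while the washout is stated for the cells in general. Libraries were made with a NEBNext Ultra II RNA kit per the labels, which do not state whether strand was kept.

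Samples were grouped by the library name in the sample description. The titles disagree with it for 7 of the 8 libraries named TTP, which their titles call EV while giving the clone as E11 or H3. The level of ZFP36 in each library is therefore reported first.

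The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2, DESeq2 and the build GRCh38, with no roles or settings, and the gene annotation is not given in the sources used here. The authors deposited 1 table of 14857 genes with a normalized signal per library, which by its values is the read count of a gene divided by 1 size factor per library. It is called normalized counts below. Per the file headers, the table also holds the authors' log2 fold change, p-value and adjusted p of a comparison of TTP with EV. Its smallest mean over the 16 libraries was 9.68 normalized counts, so genes below some limit are not analysed here. In each library 100% of the values were whole multiples of the smallest value above 0, within 0.001, which recovers the reads. In replicates 1 and 3 of TTP_H3, however, 1 read was worth 1.009 and 0.9975, so near 1 that the match is a weaker check there than in the other libraries. The reads on the listed genes were between 14380767 and 22066098 per library. These totals cover the listed genes and are not the full depth. The 10 genes with the most reads took between 4.87% and 5.78% of them.

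The planned test was a count model. Because the table holds normalized values, the alternative named beforehand for such values was the main test, and the count model was run on the recovered reads as an added alternative. The test was limma 3.58.1 in R 4.3.3, with a robust trend, on log2(value + 1), so that fold changes of genes with few reads are understated. All 16 libraries entered 1 fit with 4 clone groups. The contrast TTP versus EV averaged the clones of each arm, and further contrasts set each TTP clone against both EV clones, EV_B against EV_A and TTP_H3 against TTP_E11. Benjamini-Hochberg adjustment over all 14857 genes was used with a threshold of 0.05. A gene was called concordant when all 4 contrasts of 1 TTP clone with 1 EV clone passed the threshold with the same sign. No filter on low values was applied. With 2 clones per arm, the p-values measure the spread between cultures of a clone and not the spread between clones.

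The method was tested on simulated data. For TTP versus EV it called 84% of genes changed 1.5-fold and 98% of genes changed 2-fold, and 5.56% of its calls were unchanged genes. The concordant rule called 70% and 84% of these genes and 0 unchanged genes. For EV_B versus EV_A, 0 genes were called with no change simulated. The simulated clones of an arm had the same means, so these values do not cover false calls from differences between clones.

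The choices in this paragraph were made before the data were examined. Named genes were the ZFP36 family, the 12 higher and 12 lower concordant genes with the largest smallest change over the 4 contrasts, the 5 genes in each direction with the largest change in each contrast within an arm, and at most 4 members of each described list. Genes without a symbol, pseudogenes, genes below a mean of 1 CPM and genes that could show the sex of a donor were left out. A total of 29 gene lists was fixed, and the 26 with at least 5 measured members were tested with camera, at a preset correlation of 0.01 and again with an estimated correlation, and with fry.

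Some genes that this rule names are not reported here. Gene positions, biotypes and 3′ UTRs were taken from GENCODE 29 on GRCh38, which may differ from the annotation the authors used. It held 14820 of the listed genes. The alternatives were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, other scalings, filters and pseudocounts, a 2-group model, reads summed per clone, each EV clone alone as control, the replicate number as a block, and leaving out each library. Confidence intervals of ratios of read numbers are exact binomial intervals at 95%, and they cover counting error only. Plots were drawn with matplotlib 3.10.9.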

Results

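Transcriptomes of MDA-MB-231 cells, an aggressive triple-negative breast cancer line, were compared between 2 clones with re-expressed TTP (E11 and H3) and 2 clones with an empty vector (A and B). Each clone was sequenced as 4 biological replicates, 16 libraries in all, with 14380767 to 22066098 reads on the 14857 listed genes. Values are normalized counts, given as mean ± SD over the 4 libraries of a clone, and adjusted p-values are from limma unless another test is named. The first principal component held 73.7% of the variance and separated the arms. The second held 11.1% and separated EV_A from EV_B.

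**Figure D1:**
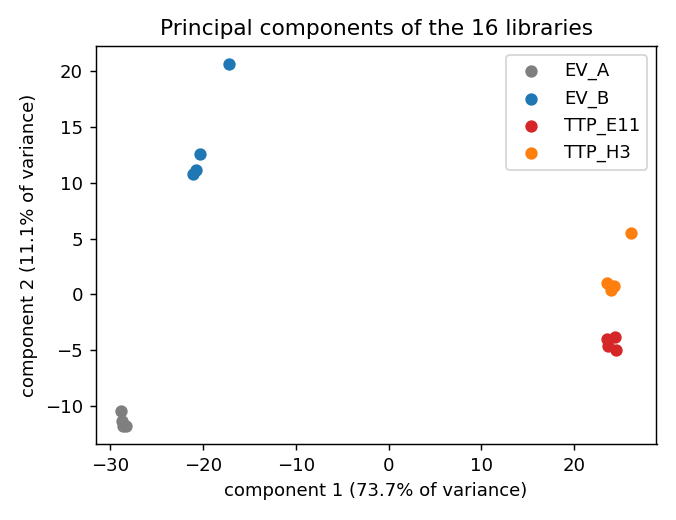
Each point is 1 library on the first 2 principal components of log2 values of genes with a mean of at least 100 normalized counts, coloured by clone. Component 1 (73.7% of the variance) separates TTP from EV clones, and component 2 (11.1%) separates EV_A from EV_B.

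The level of ZFP36 mRNA, which encodes TTP, was examined first in every library. ZFP36 (chromosome 19, 39406813 to 39409412, GRCh38) stood at 258.6 ± 26.3 normalized counts in EV_A, 222.1 ± 8.8 in EV_B, 10480 ± 337 in TTP_E11 and 14370 ± 811 in TTP_H3 (SD, n = 4 each, limma on all genes). The ratio of the arm means was 51.7. Every library named TTP was above every library named EV, with at least 559 against at most 15 CPM of the reads on listed genes. The exact two-sided permutation test of the 8 TTP against the 8 EV libraries gave p = 0.000155, the smallest it can give, and the adjusted p from limma was 5.83e-35. The permutation test treats the 16 libraries as independent, whereas they come from 4 clones. The library names, and not the 7 titles that say EV, are matched by this level. ZFP36 was higher in H3 than in E11 by 0.45 on the log2 scale (adjusted p = 1.71e-06). The related ZFP36L1 and ZFP36L2, which bind similar AU-rich elements, were lower in TTP than in EV clones, by log2 changes of -0.60 and -1.29. ZFP36L2 stood at 2210 ± 66.6 in EV_A, 1669 ± 120 in EV_B, 742 ± 39.7 in E11 and 830.6 ± 42.6 in H3.

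**Figure D2:**
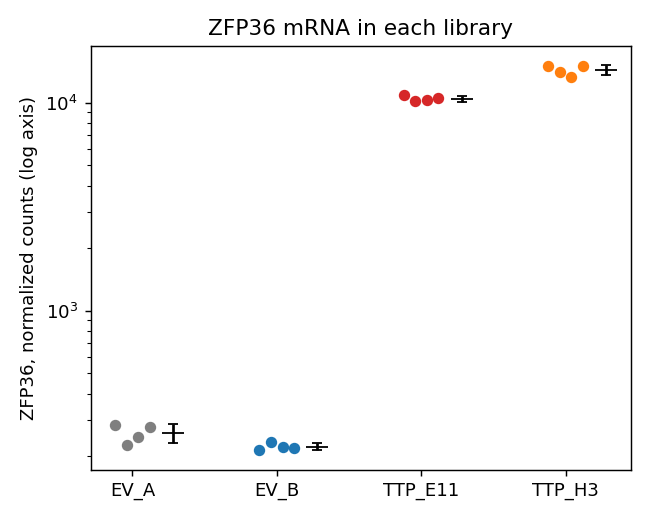
Normalized counts of ZFP36 on a log axis, with 1 point per library and the mean ± SD of the 4 libraries of a clone in black. The TTP clones average 10480 and 14370, and the EV clones 258.6 and 222.1.

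To ask which transcripts differed with TTP whichever clones were compared, concordant genes were counted. There were 5713 of them among 14857 genes (38.5%), of which 2818 were higher and 2895 lower in TTP. With a change of at least 1 on the log2 scale in each of the 4 contrasts, 435 were higher and 100 lower. In the averaged contrast 10405 genes passed the threshold, 5261 higher and 5144 lower. The same count was 5468 between EV_B and EV_A, 2 clones that both lack the TTP plasmid. That contrast sets 4 libraries against 4, and the averaged one 8 against 8. The 4 contrasts of 1 TTP clone with 1 EV clone, also 4 against 4, gave 8819 to 9503. With reads summed per clone, so that 2 clones stood against 2, edgeR called 4375 genes. The authors' deposited table called 4750 genes higher and 4710 lower at an adjusted p under 0.05, and 9452 of these 9460 calls passed with the same sign in the limma fit. Each arm held 2 clones, and maintenance in doxycycline is stated for the TTP clones alone, so TTP, clone and doxycycline history were not separated.

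Among the higher concordant genes with the largest smallest change, MMP1, an interstitial collagenase, rose from 42.33 ± 8.24 in EV_A and 201.2 ± 74.9 in EV_B to 5450 ± 202 in E11 and 7384 ± 2780 in H3 (log2 change 6.09 ± 0.179 SE, adjusted p = 1.34e-12). KISS1, which encodes the kisspeptin precursor and is known as a metastasis suppressor, rose from 25.89 ± 1.84 and 50.93 ± 5.62 to 1446 ± 57 and 2312 ± 1310. In replicate 3 of H3, which stood apart from the other libraries of its clone, MMP1 was at 11560 and KISS1 at 4275. That library also lay apart from the other 3 of H3 for PDE1C (176.6), SEL1L3 (647.4), ARTN (111.7), FLG (121.7) and GGT5 (19.95), which are named below. The D-type cyclin CCND2 rose from 5.012 ± 0.551 and 5.173 ± 2.97 to 196.8 ± 15.7 and 187.3 ± 12.7. FRMPD4, a scaffold protein, rose from 1.325 ± 1.12 and 11.22 ± 3.12 to 488.1 ± 27 and 443.3 ± 27.8. SEL1L3 and EMB, the latter encoding the membrane glycoprotein embigin, had log2 changes of 5.56 and 5.17.

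Several genes had almost no reads in EV clones. NKX2-1, a homeobox transcription factor of lung and thyroid, had 1 read over the 8 EV libraries and 325 over the 8 TTP libraries, a ratio, scaled by the size factors, of 332 with a counting interval of 59.1 to 13100. MYCT1 had 6 EV and 1091 TTP reads (ratio 185, interval 84.9 to 507). The phosphodiesterase PDE1C had 8 and 921 (ratio 117, interval 59.4 to 273). CASP1, the inflammatory caspase, had 9 and 499 (ratio 56.6, interval 29.6 to 124). CARD16 had 6 and 352, but it lies beside CASP1 on chromosome 11 and resembles it closely, so reads of this pair are uncertain.

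THBS2, a matricellular thrombospondin, fell most among the lower genes named, from 381.1 ± 17 in EV_A and 346.4 ± 53.2 in EV_B to 46.35 ± 3.18 in E11 and 13.36 ± 4.3 in H3 (log2 change -3.82 ± 0.109 SE, adjusted p = 9.99e-24). FLG, which encodes filaggrin of the cornified epidermis, fell from 1328 ± 37.9 and 1227 ± 55.1 to 228.1 ± 15.2 and 318.3 ± 132. The cyclin-dependent kinase inhibitor CDKN2D fell from 797 ± 42 and 680.4 ± 59.7 to 196.3 ± 6.9 and 182.5 ± 42.6. PHLDA2, an imprinted growth regulator, fell from 1341 ± 74 and 1457 ± 59.7 to 307.7 ± 31.3 and 396.2 ± 77.9. GJB2 (connexin 26), the neurotrophic factor ARTN, GGT5, EVI2B, MYL1 and SLCO4A1 were lower by log2 changes of -1.75, -1.64, -2.75, -1.81, -1.91 and -1.93. The noncoding LINC01505 was lower by a log2 change of -2.18. IGFL2-AS1 was lower by a log2 change of -3.46, but it is an antisense gene and strand is not stated for the counting.

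**Figure D3:**
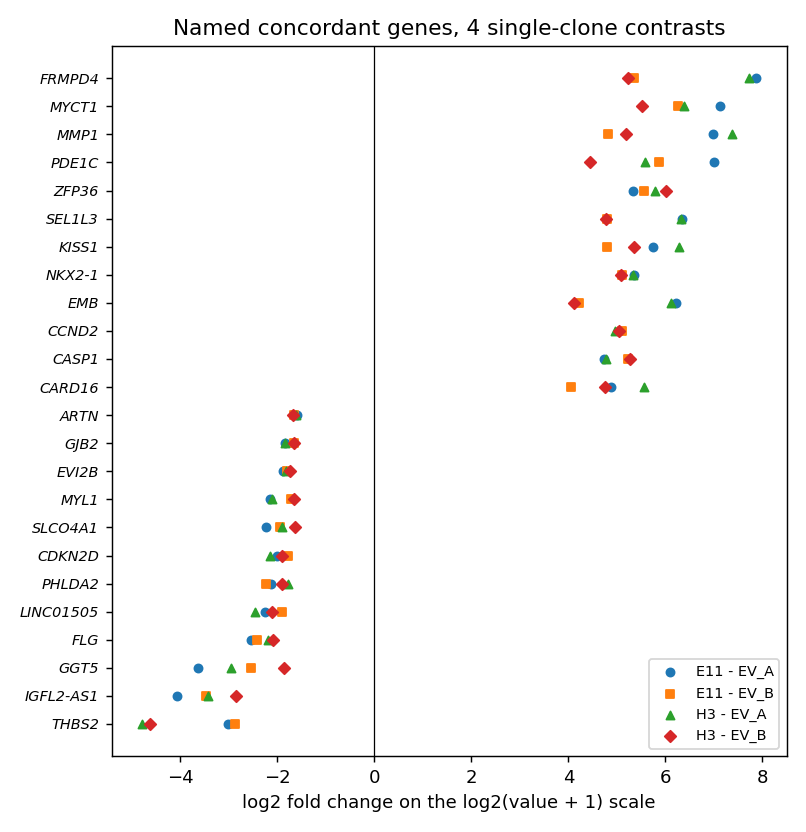
Log2 fold changes, on the log2(value + 1) scale, of the 12 higher and 12 lower named genes in each of the 4 contrasts of 1 TTP clone with 1 EV clone. Each gene keeps its sign in all 4 contrasts, from 7.87 for FRMPD4 in E11 against EV_A to -4.78 for THBS2 in H3 against EV_A.

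Of 25 measured genes on a fixed list of reported TTP targets, 9 were higher and 13 lower in TTP, and 3 and 11 of these were concordant. Among the lower ones LIF, a cytokine, fell from 885 ± 39 in EV_A and 822.8 ± 29.3 in EV_B to 288.2 ± 5.74 in E11 and 380.4 ± 31.8 in H3. The kinase PIM1 fell from 1390 ± 46.2 and 1454 ± 74.5 to 673.6 ± 43.4 and 628.5 ± 74.5. MMP1 and the phosphatase DUSP1 (log2 change 1.16) were higher. Over all 14857 genes, 2818 were concordant higher and 2895 concordant lower. The median of the list was -0.20 and its mean 0.09, which includes MMP1 at 6.09. Camera did not place the list apart from other genes (adjusted p = 0.15, or 0.357 with an estimated correlation). By fry it was lower (adjusted p = 2.3e-11), but 22 of the 26 lists passed by fry.

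Genes of G2 and mitosis were lower in TTP. Of 40 measured, 38 fell and 1 rose, with 29 concordant, a median log2 change of -0.41 and a camera adjusted p of 6.73e-14, but an adjusted p = 0.329 with an estimated correlation. HMMR, a spindle-associated receptor, fell from 380.6 ± 32.5 and 439.9 ± 21.2 in the EV clones to 194.9 ± 6.87 and 209.1 ± 7.07 in E11 and H3. The mitotic cyclin CCNA2 fell by 0.72 on the log2 scale, with an annotated end that overlaps EXOSC9 on the other strand. The kinesin CENPE and the cytokinesis protein ANLN had log2 changes of -0.68 and -0.64. Of 12 measured replication-dependent histone genes, whose sequences are similar, 9 fell and 0 rose, with a median of -0.64 (camera adjusted p = 0.00308, or adjusted p = 0.329 with an estimated correlation). HIST1H2AC and HIST1H1C had log2 changes of -0.98 and -0.86. The EV clones also differed in both lists, EV_B being above EV_A by medians of 0.11 and 0.29 (camera adjusted p = 0.000109 and 0.03). Those were adjusted p = 0.282 and 0.273 with an estimated correlation. Of 40 genes of G1/S and replication, 20 rose and 14 fell (camera adjusted p = 0.411). Among them CCND1 fell from 15510 ± 275 and 17450 ± 672 to 7561 ± 78.5 and 8381 ± 428.

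Genes of hypoxia and glycolysis were lower as well, with 30 of 35 fallen, 3 risen and 18 concordant (median -0.40, camera adjusted p = 1.23e-08, or adjusted p = 0.329 with an estimated correlation). The glucose transporter SLC2A1 fell from 17140 ± 168 and 19710 ± 365 to 9316 ± 226 and 8984 ± 900, and VEGFA fell from 4063 ± 192 and 4556 ± 149 to 2079 ± 111 and 2507 ± 468. The enolase ENO2 and the glycolytic regulator PFKFB3 had log2 changes of -1.33 and -0.98. Of these 35 genes, 23 were lower in EV_B than in EV_A and 4 were higher (median -0.27, camera adjusted p = 2.84e-09, or adjusted p = 0.191 with an estimated correlation). Of 25 genes of cholesterol synthesis and its regulation, 19 fell and 3 rose in TTP, with 11 concordant (median -0.27, camera adjusted p = 0.000817, or adjusted p = 0.659 with an estimated correlation). INSIG1, a sterol-sensing regulator of this pathway, fell from 3705 ± 208 and 2305 ± 636 to 1434 ± 34.3 and 1231 ± 54, and the sterol carrier STARD4, which has an annotated antisense gene, fell by 1.37 on the log2 scale. Between the EV clones 10 of these genes were lower in EV_B and 2 higher. Of 24 chaperones and other genes of the endoplasmic reticulum, 17 fell and 2 rose in TTP (median -0.25, camera adjusted p = 0.000817, or adjusted p = 0.329 with an estimated correlation), among them EDEM1 and CANX with log2 changes of -0.62 and -0.41. Of these, 10 were lower and 0 higher in EV_B than in EV_A.

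Messenger RNAs of cytosolic ribosomal proteins were higher in TTP, with 54 of 56 risen, 0 fallen and 38 concordant (median 0.24, camera adjusted p = 8.25e-14, or adjusted p = 0.357 with an estimated correlation). RPS27 rose from 5767 ± 156 and 6456 ± 239 to 8173 ± 345 and 7761 ± 493. Many of these genes have near-identical pseudogenes that can share their reads. The same list was higher in EV_B than in EV_A for 52 of 56 genes (median 0.21, camera adjusted p = 1.14e-22, or adjusted p = 0.191 with an estimated correlation). Of 13 mitochondrially encoded genes 8 rose and 0 fell in TTP, with 2 concordant (median 0.15, camera adjusted p = 0.0282, or adjusted p = 0.659 with an estimated correlation). Of 8 measured luminal mammary markers 7 fell and 0 rose, with 2 concordant, NAT1 and XBP1 (median -0.53, camera adjusted p = 0.0411, or adjusted p = 0.357 with an estimated correlation). This list did not pass at a pseudocount of 0.1 (median -0.51, adjusted p = 0.0621) or without replicate 4 of EV_A (median -0.52, adjusted p = 0.0509), and 4 of its genes were lower in EV_B than in EV_A. Of the 7, TFF1 was at 37.42 ± 2.42 in EV_A but 0.265 in EV_B, below E11 (2.12) and H3 (2.95), and it did not pass at a pseudocount of 0.1 (limma adjusted p = 0.386) or with edgeR (0.832) or DESeq2 (0.602).

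These 8 lists of the 26 tested passed with camera at the preset correlation, and 0 passed with an estimated one, where 3 had an unadjusted p under 0.05. With H3 alone against EV, 6 lists passed at the preset correlation, and the mitochondrial and luminal lists did not (adjusted p = 0.123 for both). By fry, which asks only whether the genes of a list move one way on balance, 22 passed. The remaining 18 lists did not pass camera, with adjusted p between 0.0775 for antigen presentation and 0.975 for p53 targets. Adjusted over the list alone, the counts of higher and lower genes in TTP versus EV were those given here for every list described. In EV_B versus EV_A, 16 of the 26 lists passed camera at the preset correlation and 2 with an estimated one. The cholesterol, endoplasmic reticulum and luminal lists were lower in EV_B at the preset correlation (camera adjusted p = 0.0227, 0.000939 and 0.001). With an estimated correlation these were adjusted p = 0.605, 0.191 and 0.191.

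**Figure D4:**
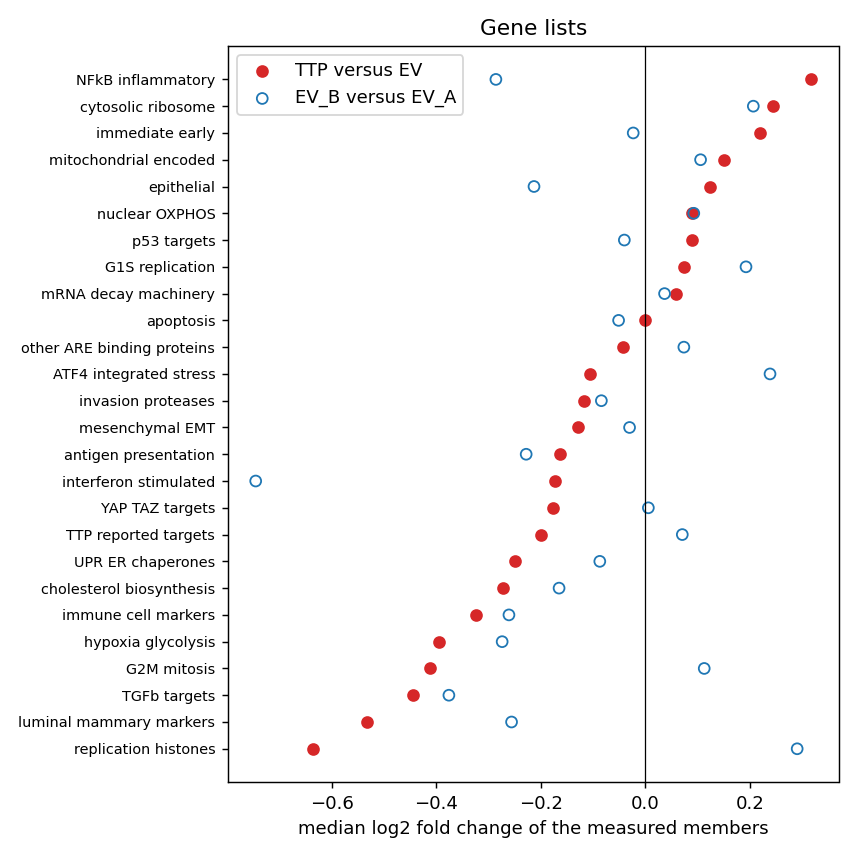
Median log2 fold change of the measured members of each tested list, in TTP versus EV (filled) and in EV_B versus EV_A (open). The G2 and mitosis list lies at -0.41 and 0.11, and the ribosomal list at 0.24 and 0.21.

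Among lists that did not pass, single members moved in both directions. In the mesenchymal list CDH2 (N-cadherin) rose from 24.01 ± 3.18 and 40.24 ± 4.36 to 144.4 ± 5.57 and 295.9 ± 52.7, TAGLN (transgelin) rose by a log2 change of 2.44, and S100A4 fell from 8842 ± 311 and 4931 ± 622 to 1699 ± 124 and 2832 ± 421. In all, 10 of its 30 measured genes rose and 16 fell, with a median of -0.13 but a mean of 0.06 (camera, lower, adjusted p = 0.394). In the list of NF-kB and inflammatory genes, 13 of 23 rose and 8 fell (camera adjusted p = 0.186), with IL32 and TRAF1 higher by log2 changes of 1.94 and 1.47. Of markers of other cell types, 5 immune, 2 endothelial and 1 embryonic kidney gene were measured. Of the immune genes, CSF1R was lower by a log2 change of -1.17 and 4 did not pass (camera adjusted p = 0.503). CSF1R stood at 120.3 in EV_A and 62.68 in EV_B, so the EV clones also lay apart. ESAM and GATA2 were higher by 0.71 and 0.85, and KDR, a VEGF receptor, rose from 46.59 ± 4.76 and 42.43 ± 9.34 to 153 ± 11.2 and 104.5 ± 13.6.

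To see whether both TTP clones showed these changes, each was set against the EV clones. E11 gave 9598 genes (4846 higher, 4752 lower) and H3 gave 9612 (4853 higher, 4759 lower). Shared calls numbered 4088 higher and 4012 lower, where independent lists would share 1583 and 1522. These lists share their controls. With the controls split, E11 against EV_A and H3 against EV_B shared 3346 higher and 3350 lower (1408 and 1380 for independent lists), and E11 against EV_B with H3 against EV_A shared 3144 and 3188 (1422 and 1399). The correlation of the log2 changes across genes was 0.89, against 0.333 simulated with no effect because the controls are shared. The covariance was 0.338, against 0.00569 simulated, and the difference between the EV clones would bring 0.0304. With the controls split, E11 against EV_A and H3 against EV_B gave a covariance of 0.313 and a correlation of 0.779, and E11 against EV_B with H3 against EV_A gave 0.302 and 0.733. These values are across genes, and genes are not independent replicates.

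The difference between the TTP clones was tested directly. In H3 versus E11, 1735 genes passed, 944 higher and 791 lower, and 108 of these changed by at least 1 on the log2 scale. The ectodysplasin gene EDA was at 138.1 ± 12.5 in H3 and 5.888 ± 1.53 in E11, and CPNE7 (copine 7) at 150.8 ± 26.7 and 8.096 ± 3.52. GRAMD1B, TESPA1 and the mucin MUC4 were higher in H3 by 4.24, 3.69 and 3.42 on the log2 scale. VWA5A was lower in H3, at 13.12 ± 7.79 against 181.9 ± 11 in E11, and APBA2 at 18.97 ± 13.9 against 118.7 ± 13.1. APBA2 did not pass at a pseudocount of 0.1 (limma adjusted p = 0.0633). The immunoglobulin genes IGHV3-15, IGHG2 and IGLC3 were also lower in H3. IGHV3-15 (chromosome 14, 106153624 to 106154163) was at 4.281 ± 0.31 in H3 and 454.2 ± 8.92 in E11, and IGLC3 had 0 reads in H3 and 321 in E11. Immunoglobulin genes resemble each other, so the gene each read came from is uncertain. The count was 1118 without replicate 2 of E11. With the libraries that stood apart left out (replicate 4 of EV_B and replicate 3 of H3, a choice made after seeing the data) it was 2851.

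As a background without introduced TTP, EV_B was compared with EV_A. A total of 5468 genes passed, 3003 higher and 2465 lower in EV_B, and 81 and 215 of these changed by at least 1 on the log2 scale. IL11, a cytokine, was at 281.4 ± 32.1 in EV_B and 29.39 ± 5.26 in EV_A. FRMPD4, MMP1, GPR65 and COL11A1 were also higher in EV_B, by log2 changes of 2.51, 2.18, 2.29 and 2.10. CA9, the hypoxia-induced carbonic anhydrase, was at 38.84 ± 12.3 in EV_B and 239.7 ± 17.4 in EV_A. SPON2 was at 22.61 ± 6.51 and 140.9 ± 13.2. PADI4 had 4 reads over the EV_B libraries and 378 over those of EV_A. IGHG2 was at 5.801 ± 0.378 in EV_B and 511.5 ± 32.4 in EV_A, and IGLC3 had 3 and 385 reads. Of 39 interferon-stimulated genes, 33 were lower and 0 higher in EV_B (median -0.75, camera adjusted p = 2.4e-22, but adjusted p = 0.106 with an estimated correlation), among them IFITM1 with a log2 change of -1.09. In TTP versus EV 10 of these genes rose and 17 fell (camera adjusted p = 0.411). Of 31 genes of the integrated stress response, 19 were higher and 2 lower in EV_B, a call that held with an estimated correlation (adjusted p = 0.0489), as did that of the inflammatory list, with 9 of 23 lower and 2 higher (adjusted p = 0.0489). Adjusted over the list alone, 34 interferon-stimulated genes were lower, 20 stress response genes were higher and 3 lower, and 10 inflammatory genes were lower and 2 higher.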

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

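The tests of library depth and of the immunoglobulin transcripts were chosen after the results were seen. So were the limits that define a transcript as near 0 or on.

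A library far from the other 3 of its clone was sought for 26 named genes, for library totals and for each library's distance from the others. It was found in 14 of 111 groups of 4, where chance gives about 6. Replicate 3 of TTP_H3 accounted for 7 of these. It held KISS1 at 4275 (others 1620 to 1686), MMP1 at 11560 (5928 to 6076), PDE1C at 176.6 (33.22 to 45.13), SEL1L3 at 647.4 (388.3 to 419.8) and ARTN at 111.7 (81.24 to 85.79). In the same library FLG was at 121.7 (367.4 to 398.1) and GGT5 at 19.95 (58.42 to 62.29). CDKN2D was at 591.5 in replicate 4 of EV_B (701 to 717.4), and GJB2 was at 228.3 in replicate 3 of EV_B (197.5 to 201.2). The other 5 rest on 1 or 2 reads. They are CARD16 at 0.866 in replicate 3 of EV_A, MYCT1 at 1.206 in replicate 1 of EV_A and at 1.881 in replicate 4 of EV_B, NKX2-1 at 0.9513 in replicate 3 of EV_B, and PDE1C at 1.206 in replicate 1 of EV_A.

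The TTP clones differed from each other in 4 of these 26 genes. H3 minus E11 was 0.45 on the log2 scale for ZFP36 (adjusted p = 1.71e-06), 0.16 for ZFP36L2 (0.0303), -1.42 for PDE1C (0.0193) and -1.77 for THBS2 (6.71e-10), by limma.

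Of the genes below 2 normalized counts in both EV clones, 12 reached at least 40 in a TTP clone, and 10 of these (83.3%, exact interval 51.6% to 97.9%), among them MYCT1, PDE1C, NKX2-1 and the neighbours CASP1 and CARD16, were at 10 or above in both TTP clones. In the other direction 1 gene, PADI4, was near 0 in both TTP clones and on in 1 EV clone. The ratio of median reads, TTP over EV, was 0.897, which argues against depth, and 0% of the 10 genes lay in runs of 50 neighbouring genes with a median above 0.3, which argues against gained segments of about that many genes. Smaller segments stay open, since such runs would not show them. CASP1 and CARD16 were 2 genes within 1 gene of each other (0.012 expected for genes placed independently). They resemble each other closely and reads of this pair are uncertain, so they may not be 2 separate cases. SALL2, NFATC4, NKX2-1 and AL589743.1, 4 of the 10, lay on chromosome 14. They lay apart there, starting at 21521081, 24365673, 36516392 and 19268853, and the number expected on 1 chromosome was not tested. A founder cell shared by the TTP clones would give a share such as 83.3%, but so would TTP itself, and the design does not separate them (the share was between 50% and 100% at other limits).

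IGHG2 and IGLC3 were high in EV_A and E11 and near 0 in EV_B and H3, whereas IGHV3-15 and the nearby pseudogenes IGHV1-14 and IGHVIII-13-1 were near 0 in H3 alone (4.28, 1.32 and 0.249 normalized counts). IGKC went the other way across the same clones, at 274 in EV_A and 251 in E11 against 487 in EV_B and 403 in H3 (limma adjusted p = 3.11e-07 and 2.07e-05). The nearly identical IGHG1 and IGHG3 did not follow IGHG2, since the larger of their differences between these clones was 0.18 on the log2 scale, against 6.08 for IGHG2, which argues against shared reads as the source. RNA of B or plasma cells cannot be told apart from expression in the clones, because 0 of 10 marker genes of these cells are listed in the table. The pattern crosses the arms, and no biological explanation was tested.

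Whether other groupings of the libraries give as many genes was counted in 2-group limma fits. Chance assignment of single libraries can be excluded, but such splits mix the clones within each group, where the differences between clones add to the spread, so they do not exclude chance differences among clones. For TTP versus EV 1 of 100 splits gave as many, the real one with 9429 genes. The highest other, with 6995, kept 7 of the 8 libraries of each arm together, and the rest gave 0. E11 versus EV gave 8491 against at most 0, and H3 versus EV 8316 against at most 31, with 100 splits each. EV_B versus EV_A gave 5794 against at most 0, and H3 versus E11 1459 against at most 1, with 35 splits each. The concordant genes numbered 5713 against at most 0 in 100 random assignments, which mix the clones likewise. By whole clones there are only 3 splits, too few for a share under 0.05. The real split gave 10405 genes and 5713 concordant genes, and the highest others gave 4812 and 146.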

How the results depend on the processing

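The TMM scaling in limma, the edgeR fit with TMM on the recovered reads, the omission of both libraries that stood apart and the matching on AU content were chosen after seeing the data. Direction and threshold were kept by ZFP36 (log2 change 5.64 to 5.70 over the settings run) and by the nonamer genes, and 3583 of the values of named genes over the settings kept both, while 6 lost the threshold and 0 reversed. The 6 were TFF1 in 5 settings and APBA2 in H3 versus E11 at a pseudocount of 0.1. At the preset correlation the luminal list lost the threshold in 2 settings and the other 7 kept it. The edgeR fit with TMM called 10432 genes in TTP versus EV and 5783 concordant ones, and DESeq2 called 10227 and 5608. A filter of 1 in at least 4 libraries removed 0 genes, and the edgeR filter also removed none, so neither tests anything. A filter of at least 1 CPM in 8 libraries left 13573 genes, and edgeR then called 9988 genes and 5641 concordant ones.

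Counts moved by over 1.5 times in these cases. With a change of at least 1 on the log2 scale also asked for, TTP versus EV gave 974, E11 versus EV 1026, H3 versus EV 990, EV_B versus EV_A 296, H3 versus E11 108 and the concordant rule 535, by construction. With reads summed per clone TTP versus EV gave 4375, with fewer samples, and 4268 of these were concordant genes with the same sign. H3 versus E11 gave 2851 without both libraries that stood apart and 1118 without replicate 2 of E11, and the cause was not tested. The lists past the threshold numbered 8, but 0 with an estimated correlation and 16 in EV_B versus EV_A.

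Leaving out each library gave 10150 to 10517 genes for TTP versus EV, 9075 to 9882 for E11, 9164 to 9686 for H3, 4808 to 6006 for EV_B versus EV_A, 5431 to 5805 concordant genes and 7 to 8 lists. For H3 versus E11 it gave 1118 to 2261.

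Replicate numbers showed little pairing of the samples, since same-number correlations between clones ran from -0.1 to 0.137 and only 2 of 24 exceeded 0.1. In addition, 0 libraries correlated best with their own number in all other clones at once. That count is strict and would be low by chance too, so it decides little. With the replicate block TTP versus EV gave 10354 genes, E11 9557, H3 9591, EV_B versus EV_A 5420, H3 versus E11 1688, the concordant rule 5691 and the list tests 8.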

Other observations

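The matching on AU content and the listing of chromosome regions were chosen after the results were seen.

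Of 33 measured apoptosis genes, 10 rose and 16 fell in TTP, with 4 concordant higher and 11 concordant lower (camera adjusted p = 0.242). PMAIP1, which encodes the BH3-only protein NOXA, fell from 2426 ± 72.8 in EV_A and 2278 ± 220 in EV_B to 926.7 ± 65.4 in E11 and 1030 ± 35.9 in H3. Among YAP and TAZ targets, 8 of 24 rose and 13 fell (camera adjusted p = 0.185). CTGF rose from 9074 ± 260 and 9063 ± 278 to 21650 ± 163 and 18160 ± 1710, while F3, tissue factor, fell from 6230 ± 52.8 and 6690 ± 59.4 to 2676 ± 89.7 and 3296 ± 324. Of 31 genes of the integrated stress response, 9 rose and 14 fell in TTP (camera adjusted p = 0.411). Among them DDIT4, an inhibitor of mTORC1 signalling, fell from 2426 ± 146 and 2486 ± 316 to 1102 ± 19.1 and 1117 ± 53.5. Of 25 immediate early genes, 13 rose and 7 fell (camera adjusted p = 0.423). The nuclear receptor NR4A1 of this list rose from 38.79 ± 1.8 and 23.26 ± 1.8 to 112.8 ± 9.61 and 112.8 ± 20.3.

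A hypothesis is that TTP lowers mRNAs that carry its binding nonamer UUAUUUAUU in the 3′ UTR, which 1172 genes held and 11387 did not. Against genes of like 3′ UTR length, nonamer genes lay lower in TTP versus EV by a median log2 difference of -0.098 (95% bootstrap interval -0.127 to -0.069). They also lay lower in each of the 4 contrasts of 1 clone with 1 clone (permutation p = 0.0005, the smallest that 2000 permutations can give). The 4419 genes with the shorter UAUUUAU lay lower by -0.158. Permutations and interval treat genes as independent and do not measure the spread between cultures or clones, and the 4 contrasts share clones. For UAUUUAU the same permutation p was reached in H3 versus E11 at a difference of only -0.013. Matching on length kept 74.8% of the unmatched difference, which argues against 3′ UTR length as the whole source, whereas a difference that the TTP clones share by origin cannot be told apart from TTP with 2 clones per arm, although EV_B versus EV_A gave -0.005, under the size asked for beforehand. Base composition stays open: the nonamer ranked only 5 of the 36 arrangements of 2 A and 7 U (2 of the 4 lower ones hold UAUUUAU themselves), where a rank of 1 or 2 had been asked for beforehand, so the difference may belong to AU-rich 3′ UTRs in general. Matched on AU content in 5 bins and on length in 4 it was -0.066 (interval -0.102 to -0.039). Length was matched more coarsely there than in the 20 strata behind -0.098. Without any matching, camera set the nonamer genes against the other genes with a 3′ UTR. It gave p = 0.000676, or p = 0.0268 with an estimated correlation, so these values do not bear on length or AU content.

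Neighbouring genes moved together in some places. In TTP versus EV, 174 of 14784 placed genes lay in runs of 50 neighbours with a median above 0.3 and 6 in runs below -0.3, where 20 shuffled gene orders gave at most 0 in either direction. The run with the most genes held 49 on chromosome 19, from 42220271 to 44109886 (median log2 change 0.39), and another held 27, from 11483427 to 12333720 (0.47). A run of 30 lay on chromosome X, from 70290090 to 75746911 (0.31). In H3 versus EV a run of 73 genes lay on chromosome X, from 64915802 to 101396154 (0.41), and 251 genes in all lay in runs above and 19 in runs below. In E11 versus EV 144 genes lay in runs above and 0 below (at most 3 in shuffled orders), with no long run on chromosome X. H3 versus E11 had a run of 35 genes there, from 71096197 to 78659328 (0.38), so the TTP clones differed in this region. In EV_B versus EV_A 0 genes lay in runs above 0.3 and 1 in a run below -0.3.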
